A study of Mus musculus with 3 samples.

How the data were processed

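Single-cell RNA sequencing measured gene expression in brain cells of 3 groups of mice, with 1 library per group. Each library pooled the cells of 3 mice, of which about 24000 cells were loaded per the labels' protocols. The groups were wild-type mice (WT), untreated mice that carry 1 copy of the I792T mutation of the CSF1 receptor (naive I792T), and mice of that genotype after microglia replacement by bone marrow transplantation (Mr BMT I792T), in which, per the labels, a normal gene took the place of the deficient one. Per the labels' protocols, mice were perfused with inhibitors of transcription and translation, brain slices were digested with papain, protease and dispase, and debris was removed on 30% Percoll. Libraries were made with a 10x Genomics 3' kit and read from both ends on an Illumina sequencer, per the labels' protocols. How recipients were conditioned and which donors were used is not given in the sources used here.

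The deposited tables hold raw UMI counts per gene and cell barcode, written by Cell Ranger 7.0.1 per the file headers. The submitters' processing notes also name bcl2fastq 2.0.1, STAR 2.7.2 and the mm10 build. Every value in the 3 tables was a whole number, so no normalisation by the authors was undone. The tables list 32286 features, among them pEGFP_C1, an added sequence named after a plasmid that encodes the fluorescent reporter EGFP. The barcodes had been filtered before deposit, and that filter differed in effect between libraries. The smallest barcode held 2730 UMIs in WT, 500 UMIs in naive I792T and 2349 UMIs in Mr BMT I792T, and 16.0% of the naive I792T barcodes held under 2000 UMIs against 0 in the other libraries.

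Barcodes with at least 500 genes, at least 1000 UMIs and at most 20% mitochondrial UMIs were kept. These were 19648 of 19805 barcodes in WT, 13670 of 15962 in naive I792T and 19911 of 19992 in Mr BMT I792T. Doublets were called per library with scrublet in scanpy 1.11.5 (expected share 0.08) and removed. The caller marked 1911 (9.73%), 782 (5.72%) and 1645 (8.26%) barcodes in the same order, which left 17737, 12888 and 18266 cells. Counts were normalised to 10000 per cell and log-transformed, 2000 variable genes and 40 principal components were taken, and cells of all libraries were clustered together with the Leiden method at resolution 1 on 15 neighbours. No batch correction was applied. The 38 clusters were named from marker genes, and all class names below mean cells that resemble the class. The markers were set before the data were examined. The score that turns markers into names, with its limit on clusters that carry markers of 2 classes, was set after the clusters had been seen. It left clusters with 2.72% of WT, 5.14% of naive I792T and 3.76% of Mr BMT I792T cells without a name. Among these, clusters with microglia and macrophage markers beside those of another class held 0.304%, 3.11% and 1.82% of cells. With 1 library per group, a cluster held mostly by 1 library may be that library rather than a cell type.

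UMI counts were summed over the cells of a class in each library and scaled by the total UMIs of that sum to CPM. Ratios between libraries were log2 values with a pseudocount of 5 CPM on both sides, which pulls large ratios of weakly expressed genes towards 0. CPM values carry exact Poisson 95% intervals and shares of cells carry exact Clopper-Pearson 95% intervals. Intervals of log2 ratios are exact conditional ones of the count ratio without the pseudocount. All intervals, and the floor of 3 counts used where a library held 0, cover counting error only. Without replicate libraries no difference has a replicate check, and no test or p-value is given. Log2 ratios within a class used at least 200 cells in both libraries, while CPM levels and shares given for smaller classes, single clusters and cell sets had no such minimum. Shares of cells with a UMI were also computed after thinning every cell to 1000 UMIs, which left out 0 of the cells compared.

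Class comparisons asked how naive I792T differed from WT and how Mr BMT I792T differed from each of the others. Genes named in the text followed a rule set before the data were examined. It took Csf1r, Csf1, Il34 and Csf2, and the 10 highest and 10 lowest log2 ratios in the microglia and macrophage class. It also took the 3 highest and 3 lowest in oligodendrocytes, astrocytes and endothelial cells, and up to 4 members of each gene list. Genes needed at least 50 CPM and 50 UMIs in 1 of the sums (20 CPM for list members). Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, T cell receptor and predicted genes were left out, as were Xist, Tsix, Ddx3y, Uty, Eif2s3y, Kdm5d and genes whose CPM was over 10 times higher in another class of the library. Oligodendrocyte precursors had too few cells. The 22 gene lists were also set beforehand: homeostatic microglia, bone marrow-derived macrophage in brain, disease-associated microglia, interferon response, MHC class I, MHC class II, inflammatory cytokine and NF-kB, immediate early and dissociation, cell cycle, p53 target, lysosome, complement and phagocytosis, CSF1R ligand and colony-stimulating factor, cholesterol synthesis, oxidative phosphorylation, glycolysis and hypoxia, myelin, disease-associated oligodendrocyte, reactive astrocyte, astrocyte transport and metabolism, blood-brain barrier, and endothelial activation. Some genes belong to more than 1 list, such as Apoe, Axl and Lyz2. A list's median log2 ratio was placed among the medians of 10000 random lists of the same size matched on mean expression, as a description of these libraries. Members at least 1.5-fold higher or lower were counted as a statement of size. A few genes that the rule takes are not reported here. EGFP, the comparisons inside single clusters and the tests of the closing section were singled out after the data were seen.

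Genes were matched to the GENCODE vM21 annotation of the mouse genome by identifier, which gave positions for 83 of 84 genes looked up; its coordinates are those of GRCm38, the assembly that the mm10 name also denotes. The step from counts to ratios and list percentiles was tested on simulated data drawn from the sums of the microglia and macrophage class with 200 genes changed. For naive I792T over WT, over 7162 genes, 100.0% of genes raised 1.5-fold or 2-fold were recovered within 0.2 log2 units and 30.0% of those lowered 4-fold. For Mr BMT I792T over naive I792T, over 7269 genes, these shares were 100.0% and 23.3%, with 85.3% for genes raised 4-fold. For Mr BMT I792T over WT, over 7294 genes, 100.0% of genes raised 1.5-fold, 97.1% of those raised 2-fold, 73.5% of those raised 4-fold and 23.3% of those lowered 4-fold were recovered. Intervals of the count ratio, which leave the pseudocount out, held the true ratio for 86.7% to 100.0% of changed genes per fold size. A planted list reached percentile 100.0 in each comparison. Of 40 unchanged lists, 1, 2 and 0 fell outside the central 95% in the same order.

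Alternatives chosen beforehand were a stricter cell filter (at least 1000 genes, at most 10% mitochondrial UMIs), a looser one (at least 200 genes, no UMI minimum, at most 50%), doublets kept, Leiden resolution 2, a pseudocount of 1 CPM, TMM scaling (edgeR 4.0.16 in R 4.3.3, used for the factors alone), the mean of each cell's own CPM in place of the sum, and list members at 20 CPM alone. Alternatives chosen after seeing the data were a minimum of 3000 UMIs in every library, the class without its low-depth cluster, the class with border-associated macrophages, and free RNA subtracted by EGFP. The last one takes from each other class of the Mr BMT I792T library the summed profile of its microglia and macrophage class, scaled so that EGFP becomes 0. The sums of WT and naive I792T, which may hold free microglial RNA too, were not corrected. For genes of resident microglia the subtraction can therefore push ratios below 0. The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.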

Results

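Gene expression was measured in single brain cells of 3 groups of mice: wild-type mice (WT), untreated mice heterozygous for the I792T mutation of CSF1R, the receptor on which microglia depend (naive I792T), and such mice after microglia replacement by bone marrow transplantation (Mr BMT I792T). Each group was 1 library that pooled 3 mice, so no value below has a replicate and every interval covers counting error only. The libraries held 285886102 UMIs in 19805 barcodes for WT, 164545261 UMIs in 15962 barcodes for naive I792T and 247119667 UMIs in 19992 barcodes for Mr BMT I792T, from about 24000 cells loaded each. Filters and doublet removal kept 17737, 12888 and 18266 cells. Median UMIs per barcode were 9574, 7885 and 8656.5 in the same order.

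The groups set the mutation against the wild type, and untreated mutant mice against other mutant mice after replacement of their microglia. The microglia and macrophage class made up 24.2% of WT cells (95% interval 23.6 to 24.8), 25.2% of naive I792T cells (24.4 to 25.9) and 43.1% of Mr BMT I792T cells (42.4 to 43.8). A looser cell filter turned the order of the first 2, to 23.9% of WT and 21.2% of naive I792T cells. Astrocytes, at 34.05%, 44.3% and 24.0%, and neurons, at 17.3%, 9.17% and 10.4%, filled most of the rest. Oligodendrocytes were 11.3% of WT, 3.48% of naive I792T and 5.44% of Mr BMT I792T cells. T or NK cells made up 0.293% of WT (0.219 to 0.384), 0.466% of naive I792T (0.355 to 0.599) and 1.60% of Mr BMT I792T cells (1.43 to 1.80), the last being 293 cells. Border-associated macrophages, which live in the coverings and around the vessels of the brain, were 0.863%, 1.11% and 1.22%. Digestion and the density step set which cells survive, so these shares describe the suspensions rather than the tissue. The naive I792T library also held 2559 barcodes (16.0%) under 2000 UMIs, where the others held 0.

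**Figure D1:**
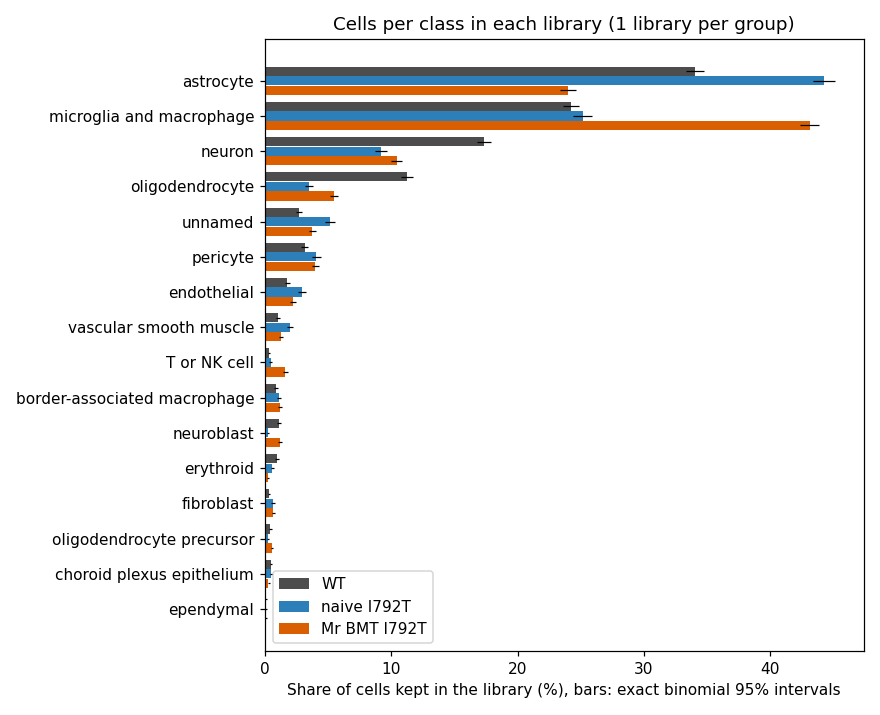
Share of the cells kept in each library that fell into each class, in percent, for WT, naive I792T and Mr BMT I792T (1 library each); error bars are exact binomial 95% intervals. The microglia and macrophage bar is at 43.1% in Mr BMT I792T against 24.2% in WT and 25.2% in naive I792T.

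Different clusters held the microglia and macrophage class in the 3 libraries. Cluster 9, of resident microglia-like cells, held 75.8% of the class in WT and 92.9% in naive I792T but 0.927% in Mr BMT I792T, which is 73 cells. Clusters 26 and 27 held 61.0% and 37.4% of the class in Mr BMT I792T, with 1 and 10 cells in WT and 0 and 7 cells in naive I792T. Cluster 10, of low depth (median 3902 UMIs in WT), held 22.2% of the class in WT, 4.66% in naive I792T and 0.127% in Mr BMT I792T. Cluster 13, led by interferon-induced genes, held 1.82%, 2.25% and 0.546%. Clusters 26 and 27 came almost wholly from 1 library.

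The comparison of naive I792T with WT asks what the heterozygous mutation does to microglia. Most of the microglial programme was at close to the same level in both libraries. Csf1r itself (ENSMUSG00000024621, chromosome 18, 61100598 to 61132149, build mm10) was at 1696 CPM in naive I792T and 1601 CPM in WT, a log2 ratio of 0.08 (0.07 to 0.10). The homeostatic microglia list had a median log2 ratio of 0.08, and 0 of its 21 genes were 1.5-fold apart. P2ry12, the purinergic receptor that steers microglial processes, was at 1875 against 1781 CPM, and Tmem119, a surface marker of microglia, at 735 against 644 CPM. The ligands were low in this class, with Csf1 at 11.5 against 11.6 CPM and Il34 at 2.01 against 2.11 CPM, and Csf2 had 0 UMIs in both.

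Among the gene lists, MHC class I had the highest median for naive I792T over WT. H2-D1 was at 301 against 182 CPM (log2 ratio 0.72) and H2-T23 at 94.7 against 60.3 CPM (0.61), although reads of these class I genes are shared with near-identical copies. B2m, the light chain of class I molecules, was at 689 against 517 CPM (0.41), and the proteasome subunit Psmb8 was at 96.7 against 69.9 CPM (0.44). The MHC class I list had a median of 0.37 (percentile 100.0 among 10000 matched random lists, as a description of these libraries), and the interferon response list a median of 0.20 (percentile 100.0) with 3 of 21 genes at least 1.5-fold higher. Among its members, Bst2, which tethers budding viruses, was at 87.9 against 58.5 CPM (0.55), Ifi204 at 20.8 against 10.5 CPM (0.74) and Ifitm3 at 27.7 against 15.4 CPM (0.68). The complement and phagocytosis list had a median of 0.28 (percentile 100.0), led by C1qa at 5009 against 3783 CPM (0.41) and C1qb at 4061 against 3089 CPM (0.39), with 0 of 15 genes past 1.5-fold. Without the low-depth cluster B2m was at 0.27, C1qa at 0.25 and C1qb at 0.24. Immediate early genes had a median of 0.34 (percentile 100.0), with the AP-1 genes Jun at 114 against 75.4 CPM (0.57) and Junb at 107 against 77.3 CPM (0.44).

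The lysozyme gene Lyz2 was at 335 against 188 CPM (0.82), and the lysosomal protease gene Ctss at 3560.0 against 2518 CPM (0.50). The lectin receptor gene Clec4a3 was at 83.6 against 57.5 CPM (0.50), and the neuronal RNA Bc1 at 89.7 against 62.3 CPM (0.49). Cebpzos was at 84.9 against 58.4 CPM (0.50), although it overlaps another gene in the annotation. Ccdc152 had the highest ratio, 89.3 against 34.1 CPM (1.27), but its last 439 bases overlap the end of the selenoprotein gene Selenop on the other strand, so the source of these reads is uncertain. The bone marrow-derived macrophage list had a median of 0.15 and the disease-associated microglia list 0.13. Members of the latter went both ways, since Lpl, the lipoprotein lipase gene, was at 7.53 against 20.6 CPM (-1.03).

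Of the genes ranked, Fkbp5 had the lowest ratio of naive I792T over WT. Fkbp5 (ENSMUSG00000024222), a chaperone gene induced by glucocorticoids, was at 417 against 753 CPM (log2 ratio -0.85). Ddit4, an inhibitor of mTORC1 induced by stress and glucocorticoids, was at 31.6 against 53.6 CPM (-0.68). The adhesion gene Sdk1 was at 99.4 against 164 CPM (-0.70), Csmd3 at 2238 against 3603 CPM (-0.69), Nav3 at 1384 against 2195 CPM (-0.66) and the histone deacetylase gene Hdac9 at 299 against 484 CPM (-0.69). Myo18b (-0.69), Plpp1 (-0.56), Upk1b (-0.56) and Cables1 (-0.55) completed the 10 lowest. The low-depth cluster held more of the class in WT than in naive I792T, and without it the homeostatic median was 0.01. The bone marrow-derived macrophage median was 0.26 with a pseudocount of 1 CPM, 0.30 with border-associated macrophages and 0.37 over members at 20 CPM alone.

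Apart from myelin, the remaining lists had medians between -0.11 and 0.18 for naive I792T over WT in this class. Medians were 0.14 for lysosome, 0.08 for inflammatory cytokine and NF-kB, 0.05 for oxidative phosphorylation, 0.02 for glycolysis and hypoxia, 0.02 for cell cycle, -0.01 for p53 target, 0.00 for the CSF1R ligand and colony-stimulating factor list, -0.08 for cholesterol synthesis and -0.11 for MHC class II. Within MHC class II, Cd74 was at 27.4 against 30.4 CPM (-0.13), a direction that turned with a stricter cell filter (0.26), with called doublets kept (0.40) and with at least 3000 UMIs (0.46). Of its 952 UMIs in WT, clusters 9, 10 and 13 held 387, 23 and 77, and the rest lay in the 1 and 10 cells of clusters 26 and 27. Within cluster 9 alone Cd74 was higher in naive I792T, at 22.2 CPM (20.4 to 24.1) against 14.8 CPM (13.4 to 16.4), as was H2-Aa, at 4.27 CPM (3.49 to 5.18) against 1.99 CPM (1.49 to 2.61). Ccl12, a monocyte-attracting chemokine gene, was at 61.0 against 39.2 CPM (0.58), and Csf2ra, a subunit of the GM-CSF receptor, at 43.1 against 33.6 CPM (0.32). Among lists of other cell types, medians were 0.18 for astrocyte transport and metabolism, 0.08 for disease-associated oligodendrocyte, 0.04 for blood-brain barrier, 0.03 for reactive astrocyte and -0.01 for endothelial activation. The myelin list stood at -0.66, with 8 of 15 genes at least 1.5-fold lower and Mal at 9.54 against 32.1 CPM (-1.35). In oligodendrocytes themselves the list had a median of 0.09, and these cells were 3.48% of naive I792T against 11.3% of WT.

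Comparing Mr BMT I792T with naive I792T asks what replacement changed in mutant brains. How recipients were conditioned is not given, so effects of conditioning cannot be separated from replacement in any comparison of Mr BMT I792T. The class carried a different macrophage profile after transplantation: genes of bone marrow-derived macrophages were higher and genes of resident microglia lower. Ms4a7 (ENSMUSG00000024672, chromosome 19, 11321039 to 11336146), a membrane gene of macrophages outside the microglial lineage, was at 916 CPM (909 to 924) against 2.45 CPM (1.87 to 3.13), a log2 ratio of 6.95. Apoe, which carries lipids between cells, was at 39262 against 794 CPM (5.62). Sall1, the transcription factor that sets microglial identity, was at 6.80 against 381 CPM (-5.03). Of the 20 genes of the bone marrow-derived macrophage list, 18 were at least 1.5-fold higher and 0 lower (median 4.11, percentile 100.0). In the homeostatic microglia list 18 of 21 genes were at least 1.5-fold lower and 0 higher (median -1.46, percentile 0.0).

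**Figure D2:**
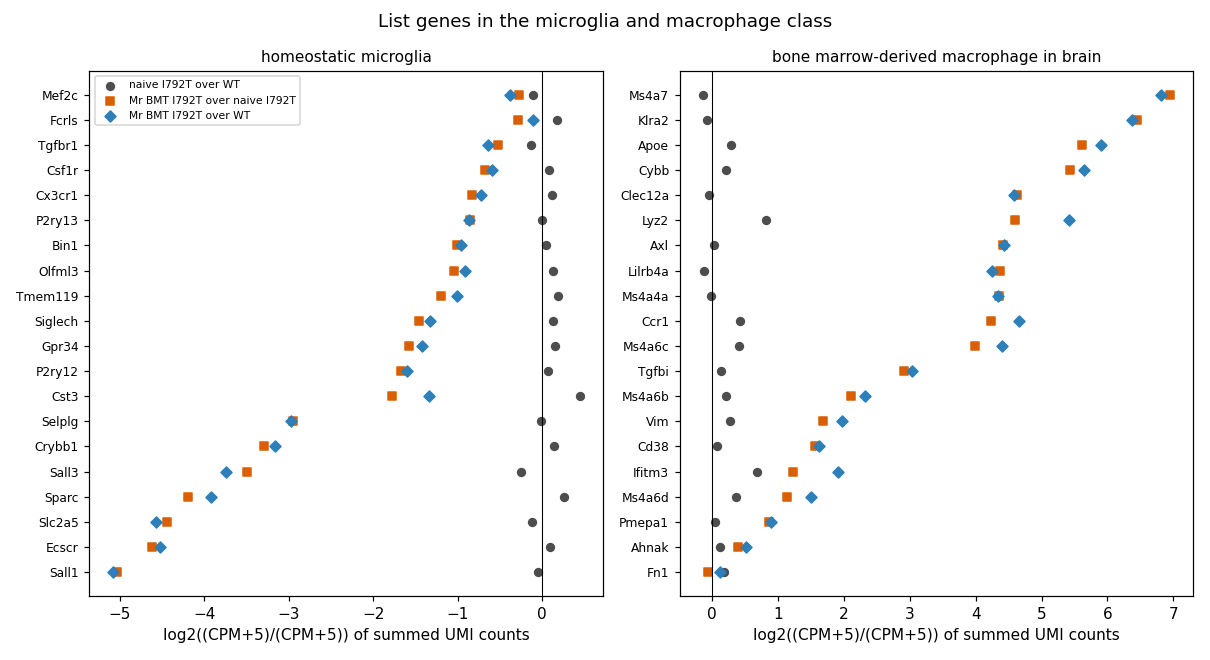
Log2 ratios of summed UMI counts (pseudocount 5 CPM) for genes of the homeostatic microglia list and of the bone marrow-derived macrophage list in the microglia and macrophage class; each symbol is 1 comparison of 2 libraries. List medians of naive I792T over WT are 0.08 and 0.15, although Lyz2 and Ifitm3 are over 1.5-fold higher in naive I792T. Sall1 is at -5.03 and Ms4a7 at 6.95 for Mr BMT I792T over naive I792T.

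Several other genes had ratios of similar size. Cybb, the catalytic subunit of the phagocyte NADPH oxidase, was at 581 against 8.56 CPM (5.43). Aoah, which inactivates bacterial lipopolysaccharide, was at 452 against 5.60 CPM (5.43), the scavenger receptor gene Msr1 at 241 against 2.68 CPM (5.00) and the integrin gene Itga4, used by leukocytes to enter tissue, at 263 against 3.71 CPM (4.95). Lyz2 was at 8215 against 335 CPM (4.60) and Adgb at 339 against 3.04 CPM (5.42). Klra2 was at 456 against 0.28 CPM (6.45) and Mndal at 156 against 0.75 CPM (4.81), both members of families of near-identical genes. The EGFP reporter was at 252 CPM against 0, at least 11.06 higher on the log2 scale at a floor of 3 counts. Beside Sall1, the lowest ratios were those of Csmd3 (-4.93), Mlph (-4.85), Ecscr (-4.62), the fructose transporter gene Slc2a5 (-4.44), the matricellular gene Sparc (-4.19), the flippase gene Atp8a2 (-4.16), the ganglioside synthase gene St3gal5 (-3.99), the protease gene Klk8 (-3.95) and Chst8 (-3.89).

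MHC class II genes were higher in Mr BMT I792T than in naive I792T, with a median of 3.68 (percentile 100.0) and 6 of 7 genes past 1.5-fold. Cd74, the invariant chain, was at 574 against 27.4 CPM (4.16), H2-Aa at 161 against 5.17 CPM (4.03) and H2-Eb1 at 139 against 5.36 CPM (3.80). The disease-associated microglia list had a median of 0.92 (percentile 100.0), with 11 of 21 genes higher and 3 lower. Beside Apoe and Lyz2, its higher members included Axl, a receptor for dying cells, at 307 against 9.70 CPM (4.41). The growth factor gene Igf1 was at 177 against 2.13 CPM (4.67). Apoe, Lyz2 and Axl also belong to the bone marrow-derived macrophage list. MHC class I had a median of 0.40 (percentile 99.96), with H2-K1 at 423 against 237 CPM (0.82) and the class I regulator Nlrc5 at 38.1 against 12.3 CPM (1.32). The interferon list had a median of 0.21 (percentile 99.2), with Bst2 at 494 against 87.9 CPM.

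Phagocytosis and lysosome genes were not of a single direction. In the complement and phagocytosis list (median -0.29), Msr1, Axl and Cd36 were higher, the last at 38.8 against 0.59 CPM (2.97), and Itgam, a chain of complement receptor 3, was at 258 against 532 CPM (-1.03). In the lysosome list (median 0.01), Cd63 was at 573 against 298 CPM (0.93), while Ctsl was at 156 against 663 CPM (-2.05) and Lgmn at 859 against 1729 CPM (-1.01). Colony-stimulating factor receptors differed too: Csf1r was at 1061 against 1696 CPM (-0.68), Csf3r at 290 against 475 CPM (-0.70) and Csf2ra at 104 against 43.1 CPM (1.18). Csf1 was at 4.19 against 11.5 CPM, Il34 at 3.95 against 2.01 CPM, and Csf2 had 0 UMIs.

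Other lists in this comparison had medians of 0.13 for inflammatory cytokine and NF-kB, -0.22 for immediate early and dissociation, -0.06 for cell cycle, 0.10 for cholesterol synthesis, 0.08 for oxidative phosphorylation, 0.49 for myelin, 0.24 for disease-associated oligodendrocyte, 0.13 for reactive astrocyte, 0.10 for astrocyte transport and metabolism, 0.07 for blood-brain barrier and 0.08 for endothelial activation. The p53 target, glycolysis and colony-stimulating factor lists had medians of 0.00. Nfkbiz was at 57.5 against 24.3 CPM (1.09) and Ccl12 at 173 against 61.0 CPM (1.43), while the chemokine gene Ccl4 was at 14.4 against 29.7 CPM (-0.84). The adhesion gene Vcam1 was at 137 against 17.2 CPM (2.67), Cp, which encodes the iron-oxidising ceruloplasmin, at 216 against 17.7 CPM (3.28), and the glutamate transporter gene Slc1a3 at 104 against 356 CPM (-1.73). With border-associated macrophages added, directions of the named genes held, but the bone marrow-derived macrophage median was 3.03 and ratios were 4.31 for Ms4a7, 3.58 for Aoah, 2.83 for Igf1, 1.83 for Cd36, 1.49 for Vcam1 and 0.93 for Ccl12. With called doublets kept H2-Aa was at 2.46 and H2-Eb1 at 2.21, at least 3000 UMIs gave 2.65 and 2.36, and with a pseudocount of 1 CPM Cd36 was at 4.65, Csf1 at -1.27 and Il34 at 0.72.

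Against WT, the same class of Mr BMT I792T asks whether replacement brought back a wild-type profile. The distance from WT was about as large as from naive I792T. The homeostatic list had a median of -1.33 (percentile 0.0; 19 of 21 genes lower) and the bone marrow-derived macrophage list a median of 4.29 (percentile 100.0; 18 of 20 genes higher). Sall1 was at 6.80 against 395 CPM (-5.08), Csmd3 at 68.6 against 3603 CPM (-5.62), Nav3 at 94.5 against 2195 CPM (-4.47), Mlph at 1.15 against 190 CPM (-4.99), Slc2a5 (-4.57), Ecscr (-4.52), Atp8a2 (-4.25), the polarity gene Pard3b (-4.21), St3gal5 (-4.10) and Chst8 (-4.07). Ms4a7 was at 916 against 3.16 CPM (6.82), Klra2 at 456 against 0.54 CPM (6.38), Apoe at 39262 against 648 CPM (5.91), Aoah (5.74), Cybb (5.64), Adgb (5.47), Lyz2 (5.41), Itga4 (5.15) and Msr1 (4.92), and EGFP was at least 11.36 higher on the log2 scale. Csf1r was at 1061 against 1601 CPM (-0.59), Csf1 at 4.19 against 11.6 CPM (-0.85) and Il34 at 3.95 against 2.11 CPM (0.33). With border-associated macrophages added Aoah was at 3.78, and with a pseudocount of 1 CPM Il34 was at 0.67.

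Both MHC lists were also above WT. MHC class II had a median of 3.43 (percentile 100.0; 6 of 7 genes higher), with Cd74 at 574 against 30.4 CPM (4.03), and MHC class I a median of 0.72 (percentile 99.99; 8 of 13 higher), with H2-D1 at 483 against 182 CPM (1.39). Medians were 0.39 for interferon response, 0.71 for disease-associated microglia, 0.15 for lysosome, 0.11 for complement and phagocytosis, 0.23 for inflammatory cytokine and NF-kB, 0.03 for immediate early and dissociation and -0.07 for myelin. The other medians were 0.29 for astrocyte transport and metabolism, 0.22 for reactive astrocyte, 0.19 for disease-associated oligodendrocyte, 0.14 for blood-brain barrier, 0.11 for oxidative phosphorylation, 0.03 for cholesterol synthesis, -0.02 for p53 target, -0.04 for cell cycle and 0.00 for glycolysis, endothelial activation and colony-stimulating factors. Ifi204 was at 105 against 10.5 CPM (2.83), Ccl12 at 173 against 39.2 CPM (2.01) and Mertk, a receptor for the uptake of dying cells, at 959 against 1863 CPM (-0.95). Fos was at 21.2 against 10.1 CPM (0.80) and Sgk1 at 70.3 against 182 CPM (-1.31).

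For single genes, Mr BMT I792T also stood apart from the other libraries in shares of cells. A UMI of Ms4a7 was found in 0.582% of WT, 1.02% of naive I792T and 94.8% of Mr BMT I792T cells of the class, and in 0.233%, 0.154% and 56.0% after thinning to 1000 UMIs. In astrocytes of Mr BMT I792T, which serve as background for free RNA, 33.1% held a UMI, or 3.22% after thinning. P2ry12 was found in 98.2%, 98.5% and 90.2% of the class, or 77.5%, 80.9% and 41.4% after thinning, against 25.5%, 30.0% and 30.1% of astrocytes, or 2.87%, 3.08% and 3.24%. Cd74 was found in 6.78%, 9.28% and 49.1% of the class, or 1.17%, 1.48% and 19.3% after thinning, against 28.9% of Mr BMT I792T astrocytes, or 2.92%. Median depth was 6820, 7501 and 7217 UMIs per cell in the class and 10760, 11088 and 11855 in astrocytes.

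EGFP had 0 UMIs in every class of WT and naive I792T, which allows up to 0.070% and 0.093% of cells with a UMI in the microglia and macrophage class. In Mr BMT I792T a UMI was found in 59.6% of that class (18.3% after thinning), in 77.9% of border-associated macrophages (32.4%) and in 29.7% of T or NK cells (9.90%). Classes taken as background for free RNA varied: astrocytes held 9.09% (0.936%), neurons 20.3% (0.998%) and pericytes 7.67% (2.06%). Among small classes, choroid plexus epithelium held 25.5% (0.0% after thinning) in 51 cells and ependymal cells 28.6% (7.14%) in 14 cells. Oligodendrocyte precursors held 12.9% (5.94%, 2.21 to 12.5), which overlaps the interval of T or NK cells after thinning (6.73 to 13.9). The labels do not say which cells carry the reporter.

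**Figure D3:**
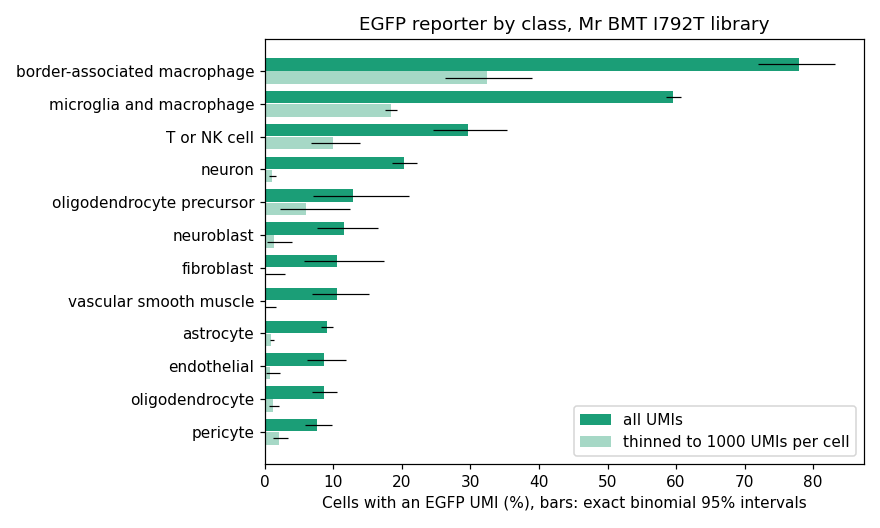
Share of cells with an EGFP UMI in each class with at least 100 cells of the Mr BMT I792T library, in percent, with all UMIs and after thinning to 1000 UMIs per cell; error bars are exact binomial 95% intervals. Border-associated macrophages are at 77.9%, microglia and macrophages at 59.6% and T or NK cells at 29.7%, beside neurons at 20.3% and astrocytes at 9.09%.

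In oligodendrocytes, myelin genes were near the same level in the 3 libraries. The myelin list had medians of 0.09 for naive I792T over WT, -0.13 for Mr BMT I792T over naive I792T and 0.03 for Mr BMT I792T over WT, with 0 of 15 genes past 1.5-fold in each. Mbp, which encodes myelin basic protein, was at 4061, 4055 and 3428 CPM in WT, naive I792T and Mr BMT I792T. The cholesterol synthesis list had medians of 0.09, 0.01 and 0.08, and Hmgcs1 was at 127, 151 and 178 CPM, although its ratio of Mr BMT I792T over naive I792T, 0.24, was -0.013 with the mean of each cell's CPM. Naive I792T over WT was highest for Hopx, at 169.8 against 84.6 CPM (0.96), Cyp27a1 (0.65) and Traf5, at 445 against 284 CPM (0.64), and lowest for Stard13 (-0.67), Rnf220 (-0.61) and Zbtb16 (-0.55). The cell cycle inhibitor gene Cdkn1a was at 49.5 against 29.2 CPM (0.67) and the protease gene Klk6 at 83.0 against 54.3 CPM (0.57). Clusters within the class differed in share. Cluster 8, with Klk6 and Apod among its leading genes, held 9.06% of the class in WT, 12.9% in naive I792T and 16.7% in Mr BMT I792T. In the same order cluster 15, with a median of 3990 UMIs, held 37.0%, 23.6% and 45.7%, and cluster 7 held 53.9%, 63.5% and 37.6%. Whether ratios of the class reflect this mix was not tested.

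The disease-associated oligodendrocyte list was higher in Mr BMT I792T, with a median of 0.63 against naive I792T (6 of 12 genes higher) and 0.84 against WT (7 higher, 1 lower). Klk6 and Apod of this list are among the leading genes of cluster 8, which held more of the class in Mr BMT I792T. The complement gene C4b was at 76.2 CPM against 31.6 CPM in naive I792T (1.15) and 27.1 CPM in WT (1.34), and B2m at 71.6 against 30.9 CPM (1.09) and 24.0 CPM (1.40). Ctss, at 233 against 48.0 CPM (2.17), Apoe, at 4751 against 1185 CPM (2.00), Ctsd, at 416 against 120.1 CPM (1.75), and Tmem176a, at 50.2 against 4.82 CPM (2.49), are also abundant in macrophages, and EGFP was at 13.7 CPM in these cells. After free RNA was subtracted by EGFP the medians were 0.17 and 0.47, and ratios over naive I792T were 0.14 for B2m, 0.33 for Ctss, 0.69 for Ctsd, 1.14 for Apoe and 1.56 for Tmem176a. Over WT B2m was at 0.45 after the subtraction. For B2m over naive I792T the stricter cell filter gave 0.70. Lowest were Traf5 (-0.85), Bfsp2 (-0.75) and Ide (-0.75) against naive I792T, and Fbn2 (-0.94), Nfkbia (-0.93) and Ddit4 (-0.91) against WT.

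In endothelial cells, activation genes were higher in naive I792T than in WT, and genes of other cell types differed too. The endothelial activation list had a median of 0.44 over WT (percentile 100.0), with 5 of 11 genes at least 1.5-fold higher and 0 lower. The adhesion genes Vcam1, at 139.8 against 64.8 CPM (1.05), and Icam1, at 30.4 against 12.5 CPM (1.01), were among them, with Vwf, the von Willebrand factor gene, at 327 against 153 CPM (1.07) and Lrg1 at 31.6 against 6.09 CPM (1.72). The interleukin 1 receptor gene Il1r1 was at 446 against 154 CPM and Adgrg6 at 51.8 against 5.01 CPM, while AY036118, a transcript of the ribosomal RNA locus, had a ratio of 1.64. The mural cell genes Rgs5, at 169.8 against 864 CPM (-2.31), and Cald1 (-1.29) were lower, as were Pld1 (-1.25) and Il34, at 5.84 against 42.2 CPM (-2.12), a gene at 624 CPM in WT pericytes. The homeostatic microglia list had a median of -0.59 (11 of 21 genes lower), with Csf1r at 28.8 against 71.2 CPM, the myelin list -0.50 (7 of 15 lower, 1 higher) and the immediate early and dissociation list 0.14 (4 of 15 higher). Cells with at least 3000 UMIs gave -0.63 for Cald1 and -0.12 for Pld1, and the mean of each cell's CPM gave 0.67 for Icam1 and -0.79 for Pld1. That mean gave 1.645 for Adgrg6, against 2.504 from the sums. With called doublets kept Pld1 was at -0.77. The class held 376 cells in naive I792T and 314 in WT, all in 1 cluster, so kinds of endothelial cell within it were not separated.

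In Mr BMT I792T part of this endothelial pattern was lower than in naive I792T, and MHC class II genes were higher. Lrg1 was at 2.52 CPM (-2.28 against naive I792T), Vwf at 166 CPM (-0.95), Il1r1 at 178 CPM (-1.30) and Adgrg6 at 13.7 CPM (-1.60), and AY036118 had a ratio of -1.09. Icam1, at 24.3 CPM, and Vcam1, at 121 CPM, stayed above WT (0.74 and 0.86), although the mean of each cell's CPM gave 0.21 for Icam1. The activation list had a median of -0.20 against naive I792T and 0.12 against WT. Cd74 was at 118 CPM against 3.12 CPM in naive I792T (3.93) and 3.22 CPM in WT (3.91), H2-Ab1 at 42.8 CPM, H2-Eb1 at 49.0 CPM and H2-Aa at 37.2 CPM. The MHC class II list had medians of 2.31 and 2.72 (5 of 7 genes higher in each), and 1.92 and 2.46 after free RNA was subtracted by EGFP. Genes of another cell type differed here too, since the myelin list had a median of 0.77 over naive I792T, and 0.65 after the subtraction. Apoe (2.53 against naive I792T, 2.81 against WT), Tmem176a (1.60 against WT) and Mpeg1 (1.48) are macrophage genes, Cck (2.24) and Hpgds (1.91) were also higher than in naive I792T, and Stra6 (-1.20), Gkn3 (-1.16) and Cpm (-0.86) were lowest against WT. The same subtraction left Apoe at 1.39 and Hpgds at 0.85 over naive I792T, and Apoe at 1.66, Tmem176a at 1.01 and Mpeg1 at 0.28 over WT. Lrg1 was at -0.99 with called doublets kept, Gkn3 at -0.45 with the mean of each cell's CPM and Cpm at -0.52 with at least 3000 UMIs. Blood-brain barrier genes had medians of 0.06, -0.07 and -0.03 in the 3 comparisons with 0 of 13 past 1.5-fold, and Cldn5, the main tight junction gene, was at 2843, 2473 and 2421 CPM in WT, naive I792T and Mr BMT I792T.

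In astrocytes, naive I792T over WT was highest for Bc1 (0.58), the ion channel gene Asic2 (0.57) and Pde10a (0.55), and lowest for Slco1b2 (-0.72), Iqck (-0.46) and the survival gene Bcl2l1 (-0.45). The reactive astrocyte list had medians of 0.01, 0.19 and 0.18 in the 3 comparisons, with 3 of 20 genes at least 1.5-fold higher in each comparison of Mr BMT I792T. Gfap, the intermediate filament of reactive astrocytes, was at 38.0, 20.2 and 28.8 CPM in WT, naive I792T and Mr BMT I792T, and C4b at 18.9, 15.4 and 28.1 CPM. The clusters of the class differed in share in the same order of libraries. Cluster 1, with Gfap among its leading genes, held 36.1%, 33.5% and 20.6% of astrocytes, and cluster 3 held 34.9%, 34.4% and 50.1%. Whether ratios of Mr BMT I792T astrocytes reflect this mix was not tested. Genes of astrocyte transport and metabolism had medians of -0.06, -0.06 and -0.11 with 0 of 12 past 1.5-fold. Mr BMT I792T over naive I792T was highest for Nupr1 (0.73), Ptgs1 (0.70) and Tmem176a (0.68) and lowest for Pde10a (-0.74), Bc1 (-0.70) and Zswim6 (-0.55). With free RNA subtracted by EGFP Tmem176a was at 0.37. Over WT it was highest for AY036118 (0.78), Tmem176a (0.69, and 0.38 after the subtraction) and Tafa1 (0.54) and lowest for Slco1b2 (-1.01), Iqck (-0.79) and D10Wsu102e (-0.68).

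Lists of macrophage genes were higher in Mr BMT I792T in oligodendrocytes, endothelial cells and astrocytes. The bone marrow-derived macrophage list had medians of 1.63, 1.74 and 0.95 over naive I792T in these classes and 1.77, 1.76 and 1.03 over WT. After free RNA was subtracted by EGFP these were 0.74, 0.58 and 0.18, and 0.62, 0.59 and 0.20. The complement and phagocytosis list went from 1.47, 1.21 and 0.66 to 0.29, 0.01 and 0.04 over naive I792T, and from 1.43, 0.96 and 0.84 to 0.28, -0.20 and 0.14 over WT. The subtraction left WT and naive I792T uncorrected. MHC class II had medians of 1.54 over naive I792T and 1.72 over WT in oligodendrocytes, and 1.20 and 1.41 in astrocytes, with 5 of 7 genes higher in each. After the subtraction 0.91 and 1.09 were left in oligodendrocytes and 0.77 and 0.97 in astrocytes. Free RNA may remain in these values. Relative to its microglia and macrophage level, the excess of Cd74 in oligodendrocytes was 1.29 times that of EGFP. There H2-Aa was at 1.92 times, and the macrophage genes Lyz2 and Ms4a7 at 1.35 and 1.28 times. In astrocytes Cd74, H2-Aa, Lyz2 and Ms4a7 were at 1.47, 2.14, 1.47 and 1.18 times.

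The ligands of CSF1R were found in several classes. Il34 was at 624, 537 and 619 CPM in pericytes and at 25.8, 23.9 and 26.9 CPM in neurons of WT, naive I792T and Mr BMT I792T. Csf1 was at 57.6, 57.4 and 72.2 CPM in oligodendrocytes, at 19.5, 17.7 and 20.5 CPM in astrocytes, at 17.9, 33.1 and 29.7 CPM in endothelial cells and at 11.6, 11.5 and 4.19 CPM in the microglia and macrophage class. Csf2 had at most 3 UMIs in any class, too few to compare.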

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

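Of the tests in this part, those of doublets and of a mixture of cells were set before their result was seen. The 3 tests of free RNA in other classes and that in resident-type cells were chosen only after the result was seen. The EGFP reporter was outside the comparisons the groups name, and it gave a signal in Mr BMT I792T above the 0 UMIs of WT and naive I792T. It reached 252.42 CPM in the microglia and macrophage class (95% interval 248 to 256), 565.5 CPM in border-associated macrophages (531 to 601) and 137.58 CPM in T or NK cells (121 to 156). Which cells were given the reporter is not stated in the labels, so EGFP marks cells with the reporter, and their origin from the graft was not tested.

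Macrophage genes were higher in the other cell classes of the Mr BMT I792T library, with Apoe at 4751 CPM in oligodendrocytes against 1185 CPM in naive I792T. Whether free RNA from the microglia and macrophage class was the source stays open: the excess of Apoe and Lyz2 in 5 classes, as a percent of their level in that class, lay within 2-fold of the percent of EGFP in 10 of 10 values, but that bound was set with the values known, and the percent of Apoe in oligodendrocytes was 8.82 (8.70 to 8.93) against 5.44 (4.52 to 6.48) for EGFP. Free RNA in proportion to EGFP did not account for Cd74 in endothelial cells, at 3.23 times the percent of EGFP. For C4b in oligodendrocytes, at 150.02 times, the outcome was fixed beforehand. C4b was at 5.47 CPM in the microglia and macrophage class, under the 31.6 CPM of naive I792T oligodendrocytes. In Mr BMT I792T oligodendrocytes it was at 76.2 CPM. H2-Aa went with Cd74 at 3.37 times in endothelial cells, and in astrocytes it was at 2.14 times. Replacement itself may have raised these genes in endothelial cells and oligodendrocytes, but other cells rich in Cd74 or C4b were not tested as a source. The mix of clusters within oligodendrocytes was not tested either, and 1 library per group leaves library effects open.

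The resident microglia-like cluster 9 held 73 cells of Mr BMT I792T, of which 29 had an EGFP UMI. EGFP in the 73 cells was at 63.4% of its level in clusters 26 and 27, which argued against free RNA as its source. All 104 EGFP UMIs lay in the 29 cells, 96 of them in 21 cells, so this says nothing of the other 44. Doublets with a macrophage and a mixture of host microglia with cells like those of clusters 26 and 27 cannot be told apart from cells of 1 kind, because choosing cells by the profile of cluster 9 already favours low Ms4a7 and high Sall1. In the 29 cells Ms4a7 was at 8.67% of its level in clusters 26 and 27, Sall1 was at 49.5% of its level in cluster 9 of WT, 193 CPM (145 to 253) against 391 CPM, and Apoe was at 10349 CPM, between 543 CPM in WT and 39678 CPM in clusters 26 and 27. The 44 cells without an EGFP UMI also differed from WT, with Ms4a7 at 40.2 against 0.57 CPM, Sall1 at 249 CPM and Apoe at 5341 CPM. Elsewhere in that library Apoe was at 3034 CPM in neurons and 5254 CPM in pericytes. Whether cells with the reporter took on a resident profile stays open.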

How the results depend on the processing

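The settings with at least 3000 UMIs in every library, without the low-depth cluster, with border-associated macrophages and with free RNA subtracted by EGFP were chosen only after the data were seen. No paired analysis was possible because each group was 1 library. The share of the microglia and macrophage class was 24.2% in WT, and 21.7% with doublets kept, 18.8% without the low-depth cluster and 25.1% with border-associated macrophages. In naive I792T it was 25.2%, and 27.2% with the stricter filter, 21.2% with the looser one, 23.6% with doublets kept, 26.4% at 3000 UMIs, 24.0% without the low-depth cluster and 26.3% with border-associated macrophages. In Mr BMT I792T it was 43.1%, and 44.1%, 35.1%, 37.3%, 40.6% at Leiden resolution 2, 39.7% at 3000 UMIs and 44.3% with border-associated macrophages. The lower shares of Mr BMT I792T went with more cells in unnamed clusters with macrophage markers: 9.84% with the looser filter, 4.56% with doublets kept, 4.93% at resolution 2 and 5.31% at 3000 UMIs, against 1.82%. The homeostatic microglia median for naive I792T over WT was 0.08, and 0.10 with TMM, 0.12 with the mean of each cell's CPM, 0.059 at 3000 UMIs and 0.01 without the low-depth cluster. Over naive I792T, Mr BMT I792T had -1.43 with border-associated macrophages, and over WT -1.34 with doublets kept, -1.34 at resolution 2, -1.44 without the low-depth cluster and -1.31 with border-associated macrophages. The bone marrow-derived macrophage median for naive I792T over WT was 0.15, and 0.26 with a pseudocount of 1 CPM, 0.30 with border-associated macrophages and 0.37 over members at 20 CPM. In the same order Mr BMT I792T had 4.37, 3.03 and 4.35 over naive I792T, with 4.03 for the mean CPM, and 4.74, 3.22 and 4.39 over WT, with 4.37 for the mean CPM and 4.36 with doublets kept. Of these medians 0 changed sign, but the order of shares turned with the looser filter, to 23.9% in WT against 21.2% in naive I792T. Subtracting free RNA turned the complement and phagocytosis median in endothelial cells over WT from 0.96 to -0.20, and the homeostatic microglia median in oligodendrocytes from 0.70 to -0.27 over naive I792T and from 0.60 to -0.21 over WT. Only Mr BMT I792T was corrected, although P2ry12 was found in 25.5% of WT and 30.0% of naive I792T astrocytes. These negative medians therefore do not show lower levels in Mr BMT I792T. Cd74 in the microglia and macrophage class for naive I792T over WT turned from -0.13 to 0.26 with the stricter filter, 0.40 with doublets kept and 0.46 at 3000 UMIs, and Hmgcs1 in oligodendrocytes over naive I792T from 0.24 to -0.013 with the mean CPM. Except for unnamed clusters, members of a set and the counts subtracted, the cause was not tested. For the named genes together, 1817 of 3108 values lay within the interval of the main count ratio, 1287 lay beyond it and 4 turned. That interval leaves the pseudocount out, so a main value can itself lie beyond it, and the 1287 overstate how far values moved. A turn was counted only where the interval excluded 0, so smaller changes of sign are not among the turns. Of list members in other classes, 57 of 3353 turned, 33 of them with free RNA subtracted. The class without clusters of border-associated macrophages, monocytes or dendritic cells gave no value, since it held none, and Leiden resolution 2 was run for shares and list medians alone. Depth limited genes near 0, such as Csf2.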

Other observations

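The test of removal by the doublet caller was set before its result was seen, while the tests of the cells it removed and of olfactory tissue, and the genes and single clusters below, were chosen only after the result was seen. Inside Mr BMT I792T the macrophages came in a pair of clusters, compared here in genes picked after the clusters were seen. Cluster 27 had Cd74 at 1130.1 CPM against 179 CPM in cluster 26, H2-Aa at 323 against 45.5 CPM, Lyz2 at 13708 against 4447 CPM and the lysosomal gene Gpnmb at 66.4 against 3.68 CPM. EGFP was at 375 against 166 CPM and Apoe at 52084 against 30759 CPM. Of the microglial genes, P2ry12 was at 420.01 against 685 CPM and Tmem119 at 355 against 284 CPM.

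Border-associated macrophages of Mr BMT I792T had the scavenger receptor gene Cd163 at 124 CPM, against 820.45 CPM in WT and 819 CPM in naive I792T, in 222, 153 and 143 cells. Cd74 was at 1594 CPM against 580.5 and 467 CPM, Lyve1 at 437 CPM against 562 and 965 CPM, and the mannose receptor gene Mrc1 at 3028 CPM against 4274 and 4325 CPM. Fkbp5, induced by glucocorticoids, was at 753, 417 and 368 CPM in the microglia and macrophage class and at 149, 103 and 103 CPM in oligodendrocytes of WT, naive I792T and Mr BMT I792T. In the same order it was at 55.7, 38.9 and 46.0 CPM in astrocytes, 53.8, 42.7 and 49.97 CPM in neurons, 66.95, 59.98 and 57.1 CPM in endothelial cells and 25.9, 20.5 and 46.2 CPM in pericytes. The glucocorticoid-induced kinase gene Sgk1 was at 182, 138 and 70.3 CPM in the microglia and macrophage class, 1148, 879 and 649 CPM in oligodendrocytes, 16.2, 8.66 and 13.4 CPM in astrocytes, 114, 116 and 112 CPM in neurons, 160.03, 142 and 136 CPM in endothelial cells and 36.3, 14.3 and 27.3 CPM in pericytes. Ddit4 was at 53.6, 31.6 and 8.32 CPM in the microglia and macrophage class, 122, 98.2 and 62.8 CPM in oligodendrocytes, 70.8, 74.9 and 64.4 CPM in astrocytes, 14.9, 13.4 and 10.9 CPM in neurons, 166, 201 and 134 CPM in endothelial cells and 66.8, 49.6 and 40.4 CPM in pericytes.

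A finer cluster of neuroblast-like cells led by Igfbpl1 held 168 cells of WT (0.947%), 112 cells of naive I792T (0.869%) and 0 cells of Mr BMT I792T, where 0 allows up to 0.0164%, and cells with UMIs of both Igfbpl1 and Sox11 were 1.64%, 1.34% and 0.279%. A companion finer cluster led by Mki67 and Top2a held 53, 42 and 19 cells (0.299%, 0.326% and 0.104%). The neuroblast class was 1.19% of Mr BMT I792T, 1.08% of WT and 0.233% of naive I792T, the last being the outlying library. Between WT and naive I792T its share did not follow that of the Igfbpl1 cluster. It therefore cannot decide whether less olfactory tissue was the cause. With doublets kept, the share of cells with both genes in Mr BMT I792T was 21.1% of that in naive I792T, with an interval that reached past the bound of 25%, so that test alone did not decide. The caller removed 4 cells with both genes from Mr BMT I792T, where 176.8 were estimated missing, a figure that mixed totals with and without called doublets. With doublets kept the share was 0.276% (0.208 to 0.359) in Mr BMT I792T against 1.31% (1.13 to 1.51) in naive I792T. That argued against the caller as the whole cause. A loss of young neurons with the transplantation, or with the conditioning before it, which is not given, may explain the gap. The region dissected and the survival of these cells in digestion stay open too with 1 library.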
